A study of Homo sapiens with 12 samples.

How the data were processed

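Total RNA from cultured SK-N-BE(2) neuroblastoma cells had been hybridised as biotin-labelled cRNA to Affymetrix Human Gene 2.0 ST arrays, 1 array per sample and 3 arrays in each of 4 groups (vehicle, 1 µM JQ1, 10 nM panobinostat, and both compounds, each for 6 h). The deposited table holds 1 value per transcript cluster (the probes that the array design assigns to 1 transcribed locus) and array, 53617 clusters by 12 arrays, and its values are taken as log2 signal intensities, since they run from 1.391 to 14.1 without zeros. The labels do not state the log base, so fold changes rest on that reading. The authors' processing notes name MAS5 and affy without a version or a role, and the background correction, summarisation, between-array normalization and genome build are not given in the sources used here. Array medians over all clusters lay between 6.119 and 6.292. Values carry no detection call or background estimate, so signal over background is unknown, and the number of arrays limits the precision.

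A probe-to-gene table named 16098 of the clusters, each with 1 gene symbol, and all of their Entrez identifiers were found in a RefSeq gene table, which supplied the gene type. Each symbol was represented by its cluster with the highest mean over the 12 arrays, which gave 14884 genes (11916 protein-coding and 1072 miRNA genes), 779 of them with more than 1 cluster. The 37519 clusters without a gene name were tested only apart from the genes. MYCN and CDKN1A have no cluster named for them in that table and were not analysed here. No gene was removed for low signal, and the authors' values were not normalised again.

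Differences were tested in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, 1 coefficient per group, no replicate term, all 12 arrays in 1 fit). 6 comparisons between groups were made, plus the interaction, which is the change with both compounds minus the sum of the changes with each compound, all on the log2 scale. The fit left 8 residual degrees of freedom and a prior of 3.457. P-values are two-sided and were adjusted by the Benjamini-Hochberg method over the 14884 genes within each comparison, and a gene was called at an adjusted p under 0.05. A change is given as log2 ± SE from limma, with n = 3 arrays per group. An exact permutation test of 3 against 3 arrays cannot give a two-sided p under 0.1, so no single gene was tested that way. The labels do not say whether the replicates of a group were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

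30 gene lists were fixed from general knowledge before the data were examined, as were the comparisons, the tests, the rule for named genes and most of the other settings tried. 29 lists had at least 5 measured members and were tested with limma's camera (preset inter-gene correlation 0.01) in the 3 comparisons with vehicle and in the interaction, adjusted over the lists within a comparison. The list of replication-independent and linker histone genes had 0 measured members and was not tested. Camera with an estimated correlation and fry were run beside it. Camera compares a list with the other genes, whereas fry tests whether a list's genes move on balance in 1 direction and compares it with no other gene. The genes named in the text are, for each comparison with vehicle, the 10 protein-coding genes with the largest rise and the 10 with the largest fall among called genes whose arrays did not overlap between the groups and whose higher group mean reached the median gene's mean of 7.238. 5 per direction were taken for the other comparisons, without the condition on overlap for the interaction. Added to these were genes chosen in advance as central to the compounds or the disease, and for each list up to 4 called members with the largest change plus at most 1 member that was not called.

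The overlap of the genes called with each compound was set beside the product of the marginal counts and beside 100 simulated draws in which both treated groups were unchanged and shared the vehicle arrays. A gene was counted as changed more by the combination than by either compound when the combination differed in the same direction from vehicle, from JQ1 and from panobinostat. Data were also simulated with independent normal noise of each gene's estimated spread and 200 changed genes. For the combination the fit called 64 of 100 genes shifted by a log2 of 0.5 and 100 of 100 shifted by 1. For the interaction it called 23 and 93, and unchanged genes called numbered 6 for the combination and 7 for the interaction. With no gene changed the fit called 0, and the list test called the shifted list in 2 of 2 tests and an unshifted list in 0 of 112. These draws lack noise shared between genes, so they do not show how often the noise of these arrays gives a false list call.

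Other settings fixed in advance were median centring or quantile normalization of the arrays, leaving out genes under the 40th percentile of mean signal, testing all clusters, a replicate term, an intensity trend with a robust prior, array quality weights, fits with only the compared groups, a 2-fold minimum change, the mean of all clusters of a gene, and leaving out each array in turn. Those chosen after seeing the data were the first component of the miRNA-gene clusters as a covariate, leaving out the 2 arrays farthest from their groups (vehicle replicate 1 and panobinostat replicate 1), and leaving out each array in the list tests. For the overlap of the compounds, the 2-fold minimum, all clusters, array weights, the intensity trend, fits of the compared groups and quantile normalization were also chosen after seeing the data. Each called number of genes or lists was recomputed over other splits of the arrays into groups of the same sizes, and the interaction, its list calls and the genes changed more than by either compound over permutations of residuals around additive effects or the larger single effect. Those permutations, a division of the vehicle arrays between the compounds and a replicate term within panobinostat status were chosen after seeing the data.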

Results

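Gene expression was measured in SK-N-BE(2) cells, a neuroblastoma line with amplified MYCN, after 6 h with vehicle, 1 µM JQ1, 10 nM panobinostat, or both compounds. JQ1 blocks the bromodomains of the BET proteins, which read acetylated histones, and panobinostat inhibits histone deacetylases (HDACs). Each of the 4 groups had 3 arrays, and 14884 genes were tested, each represented by 1 transcript cluster. Correlations between arrays over these genes were 0.991 to 0.995 within groups and 0.962 to 0.989 between groups. The first principal component of the 12 arrays held 48.4% of the variance. JQ1 and vehicle arrays did not overlap for 33.5% of genes, against 39.8% for panobinostat and 46.1% for the combination. Chance gives 10% for 3 against 3. Changes are log2 differences ± SE from limma with n = 3 arrays per group, and adjusted p-values are limma's.

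JQ1 was compared with vehicle to find the genes that respond to BET inhibition alone. HEXIM1 (cluster 16834921), which encodes an inhibitor of the elongation kinase P-TEFb, rose 3.61-fold (log2 change 1.85 ± 0.06, adjusted p = 6.4e-08). PAG1, an adaptor of Src-family kinases (4.05-fold, 2.02 ± 0.13), and AHR, a ligand-activated transcription factor (2.77-fold, 1.47 ± 0.09), rose too, as did SESN3, a sestrin (1.43 ± 0.08), and MKNK2, a kinase of the translation factor eIF4E (1.41 ± 0.08). LRRTM1, a synaptic adhesion protein (-1.88 ± 0.11), and CCL2, a chemokine (-1.88 ± 0.19), had the largest falls among the genes named here. They were followed by NPY2R, a neuropeptide Y receptor (-1.86 ± 0.09), POPDC2, a membrane protein of muscle and nerve (-1.80 ± 0.09), and DKK1, a secreted WNT antagonist (-1.74 ± 0.14). LIN28B, which blocks maturation of let-7 microRNAs, fell by 0.90 ± 0.10, and BCL2, an inhibitor of apoptosis, fell by 0.68 ± 0.09. A second, dimmer HEXIM1 cluster had a log2 value of -0.40 against vehicle that did not pass the test (adjusted p = 0.185).

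Of 14884 genes, 2627 differed between JQ1 and vehicle (1218 higher and 1409 lower), 129 of them by at least 2-fold (55 higher and 74 lower). The split turned to 1467 higher and 1326 lower when each array was centred on its median, and to 1882 and 1768 with the miRNA-gene covariate. In the list of BET proteins, P-TEFb and elongation factors, 7 of 18 measured genes rose and 1 fell (median 0.17, camera adjusted p = 0.00196, and adjusted p = 0.218 with an estimated correlation). Its members included BRD2 at 0.88 ± 0.10, CDK9, the P-TEFb kinase, at 0.36 ± 0.06, and HEXIM2, a relative of HEXIM1, at -0.79 ± 0.10. A dimmer HEXIM2 cluster was not lower, at 0.09 with JQ1 (adjusted p = 0.649 over all clusters) and 0.27 with the combination (adjusted p = 0.0444). BRD3 rose by 0.33 ± 0.06. Immediate early and AP-1 genes rose in 13 of 24 cases and fell in 0 (median 0.40, adjusted p = 8.44e-06, and adjusted p = 0.0634 with an estimated correlation). EGR1 was at 1.24 ± 0.12, IER5 at 1.07 ± 0.12 and JUND at 0.86 ± 0.10. Among 14 p53 target genes, 8 rose and 0 fell (median 0.49, adjusted p = 0.00229, and adjusted p = 0.218 with an estimated correlation). TP53INP1 was at 1.01 ± 0.12 and SESN2 at 0.91 ± 0.11. Genes reported to respond to HDAC inhibitors, fixed as a list in advance, were higher in 10 of 28 cases and lower in 1 (median 0.15, adjusted p = 0.00229, and adjusted p = 0.289 with an estimated correlation). The adrenergic transcription factors that specify the sympathetic neuroblast state went both ways, 8 of 26 falling and 3 rising (median -0.21, adjusted p = 0.00229, and adjusted p = 0.199 with an estimated correlation). LMO1 was at -1.43 ± 0.13, TFAP2B at -1.41 ± 0.09, SOX11 at 0.63 ± 0.10 and GATA3 at 0.28 ± 0.07. Adjusted over the list alone, the numbers higher and lower were 7 and 1 for the BET list, 14 and 1 for immediate early genes and 8 and 1 for p53 targets. They were 11 and 1 for the HDAC inhibitor response and 4 and 14 for adrenergic factors.

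**Figure D1:**
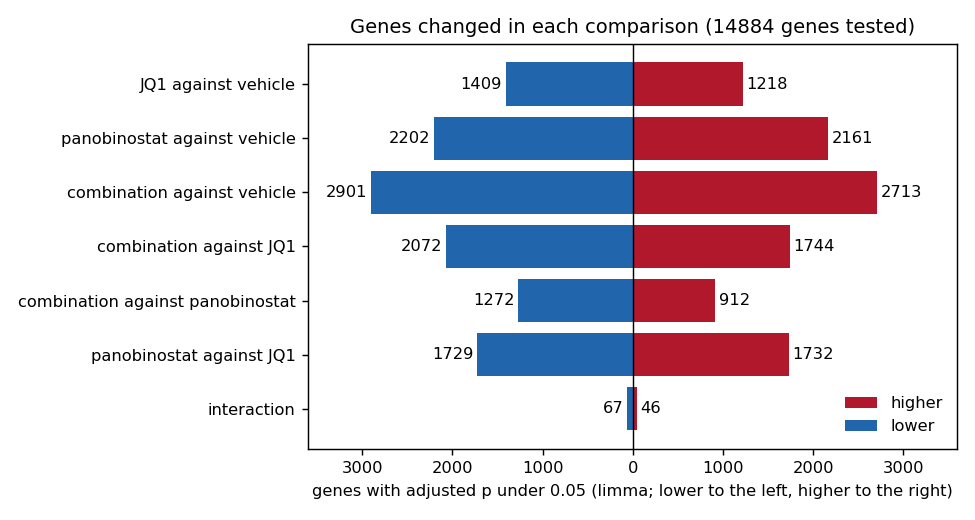
Number of genes called by limma (adjusted p under 0.05) as higher or lower in each comparison. The combination changed 5614 genes against vehicle, panobinostat 4363 and JQ1 2627, and the interaction term was called for 113.

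Panobinostat was compared with vehicle to find the genes that respond to HDAC inhibition alone. REEP6 (cluster 16856604), which encodes a membrane-shaping protein of the endoplasmic reticulum, rose 6.05-fold (2.60 ± 0.15, adjusted p = 6.07e-07). EFNA3, an ephrin ligand, rose by 2.35 ± 0.08 and HSPA2, an HSP70 family chaperone, by 2.08 ± 0.13. AHR rose by 2.04 ± 0.09 and TEC, a tyrosine kinase, by 1.76 ± 0.22. Among the named genes the largest falls were in TFAP2B (cluster 17009545), a neural crest transcription factor (5.37-fold lower, -2.42 ± 0.09, adjusted p = 8.17e-08), and LRRTM1 (-2.07 ± 0.11). Also lower were ZBTB2, a zinc finger protein (-1.86 ± 0.11), CD200, a membrane glycoprotein (-1.84 ± 0.10), KEAP1, the sensor that restrains NRF2 (-1.78 ± 0.13), and LIN28B (2.89-fold, -1.53 ± 0.10).

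Between panobinostat and vehicle, 4363 genes differed (2161 higher and 2202 lower), 121 of them at least 2-fold higher and 176 at least 2-fold lower. With the miRNA-gene covariate the split was 2425 higher and 1829 lower, after quantile normalization 2357 and 2336, and after centring each array on its median 1995 and 2500. Adrenergic transcription factors fell in 19 of 26 cases and rose in 1 (median -0.46, camera adjusted p = 2.32e-09), and this call held with an estimated correlation (adjusted p = 0.0121). Beside TFAP2B, they included TBX3 (-1.38 ± 0.07), MEIS2 (-1.11 ± 0.06), GATA3 (-1.04 ± 0.07) and HAND2 (-1.01 ± 0.08). Of 32 mitotic genes, 18 fell and 2 rose (median -0.27, adjusted p = 4.22e-05, and adjusted p = 0.45 with an estimated correlation). PLK1 was at -0.73 ± 0.10, CCNB1 at -0.62 ± 0.07 and AURKA at -0.57 ± 0.09. DNA replication genes fell in 10 of 22 cases and rose in 2 (median -0.16, adjusted p = 0.0194, and adjusted p = 0.654 with an estimated correlation). TYMS, the thymidylate synthase, was at -0.90 ± 0.06 and the replication factor GINS4 went the other way at 0.87 ± 0.11. MYC target genes of biosynthesis and growth fell in 12 of 21 cases and rose in 1 (median -0.26, adjusted p = 0.00249, and adjusted p = 0.45 with an estimated correlation). PUS7 was at -0.54 ± 0.06 and MRTO4 at -0.51 ± 0.08. Among 9 anti-apoptotic genes 6 fell and 0 rose (median -0.33, adjusted p = 0.00266, and adjusted p = 0.45 with an estimated correlation). BCL2 was at -1.19 ± 0.09, CFLAR at -0.85 ± 0.10 and BCL2L1 at -0.75 ± 0.11. HDAC inhibitor response genes rose in 13 of 28 cases and fell in 1 (median 0.35, adjusted p = 0.0013, and adjusted p = 0.45 with an estimated correlation). Adjusted over the list alone, the numbers higher and lower were 1 and 20 for adrenergic factors, 2 and 19 for mitotic genes and 2 and 10 for DNA replication. They were 2 and 14 for MYC targets, 0 and 6 for anti-apoptotic genes and 14 and 1 for the HDAC inhibitor response.

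The DNA replication call for panobinostat ended without panobinostat replicate 1 (list mean -0.122) or vehicle replicate 1 (-0.101), after quantile normalization (-0.088) and without dim genes (-0.128). With the miRNA-gene component as covariate it ended too (-0.031), as did those of MYC targets (-0.107) and anti-apoptotic genes (-0.346). That component separated all arrays with panobinostat from all arrays without it. Losses with this covariate therefore do not tell a measurement difference from treatment signal. Without the 2 arrays farthest from their groups, the calls of DNA replication (-0.095) and anti-apoptotic genes (-0.373) ended.

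The combination was compared with vehicle to show the response when BET proteins and HDACs are inhibited together. TFAP2B was 11.2-fold lower (-3.48 ± 0.09, adjusted p = 1.36e-09), LRRTM1 10.4-fold lower (-3.38 ± 0.11), and BCL2 (cluster 16855673) 5.66-fold lower (-2.50 ± 0.09, adjusted p = 7.38e-09). LIN28B fell 4.66-fold (-2.22 ± 0.10), and CCND1, the gene of cyclin D1, fell by 1.37 ± 0.08. REEP6 was 10.9-fold higher (3.45 ± 0.15) and HEXIM1 3.89-fold higher (1.96 ± 0.06), and TESK2, a kinase of the actin regulator cofilin (2.49 ± 0.14), AHR (2.39 ± 0.09) and DHRS2, a dehydrogenase (2.21 ± 0.25), rose as well. The dimmer HEXIM1 cluster went the other way with the combination (-0.68, adjusted p = 0.01). BCL2L11, whose product BIM promotes apoptosis, rose with JQ1 (0.63 ± 0.13), panobinostat (0.49 ± 0.13) and the combination (0.69 ± 0.13), although its panobinostat call was lost without vehicle replicate 3 (0.40).

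The combination and vehicle differed in 5614 genes (2713 higher and 2901 lower), 296 of them at least 2-fold higher and 465 at least 2-fold lower. With the miRNA-gene covariate 2848 were higher and 2586 lower, and after quantile normalization 2938 and 2923. Of the 26 adrenergic transcription factors 22 fell and 1 rose (median -1.03, camera adjusted p = 5.26e-13), a call that held with an estimated correlation (adjusted p = 0.00397). TBX3 (-1.91 ± 0.07), MEIS2 (-1.80 ± 0.06), LMO1 (-1.74 ± 0.13) and HAND2 (-1.23 ± 0.08) were among them. HDAC inhibitor response genes rose in 20 of 28 cases and fell in 1 (median 0.45, adjusted p = 1.41e-05, and adjusted p = 0.164 with an estimated correlation). Of 24 immediate early and AP-1 genes 14 rose and 4 fell (median 0.33, adjusted p = 0.00162, and adjusted p = 0.164 with an estimated correlation). EGR1 was at 1.71 ± 0.12, KLF2 at 1.51 ± 0.20 and FOS at 1.34 ± 0.15. A dimmer FOS cluster was at 0.17 and not called (adjusted p = 0.518 over all clusters). Of 14 p53 target genes 8 rose and 2 fell (median 0.54, adjusted p = 0.0374, and adjusted p = 0.324 with an estimated correlation). TP53INP1 was at 1.34 ± 0.12, SESN2 at 1.32 ± 0.11 and TP53I3, an oxidoreductase, at -0.78 ± 0.07. Cholesterol and sterol-responsive genes rose in 11 of 20 cases and fell in 3 (median 0.33, adjusted p = 0.0374, and adjusted p = 0.676 with an estimated correlation). VLDLR, a lipoprotein receptor (-1.07 ± 0.07), and ELOVL6, a fatty acid elongase (-1.18 ± 0.07), were lower. Mitotic genes fell in 19 of 32 cases and rose in 2 (median -0.28, adjusted p = 0.000209, and adjusted p = 0.328 with an estimated correlation). NDC80 and PLK1 were both at -0.90. DNA replication genes fell in 11 of 22 cases and rose in 4 (median -0.19, adjusted p = 0.032, and adjusted p = 0.676 with an estimated correlation). MCM5, a helicase subunit, was at -0.79 ± 0.07. MYC targets fell in 13 of 21 cases and rose in 3 (median -0.31, adjusted p = 0.022, and adjusted p = 0.549 with an estimated correlation). Of 9 anti-apoptotic genes 4 fell and 0 rose (median -0.20, adjusted p = 0.022, and adjusted p = 0.324 with an estimated correlation). CFLAR was at -1.25 ± 0.10 and BCL2L1 at -1.10 ± 0.11. Adjusted over the list alone, the numbers higher and lower were 1 and 23 for adrenergic factors, 20 and 1 for the HDAC inhibitor response, 15 and 4 for immediate early genes, 8 and 3 for p53 targets and 12 and 3 for sterol genes. They were 2 and 19 for mitotic genes, 4 and 12 for DNA replication, 4 and 13 for MYC targets and 0 and 4 for anti-apoptotic genes.

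Without combination replicate 2 the combination's list calls of p53 targets (list mean 0.431), sterol genes (0.201) and anti-apoptotic genes (-0.569) were lost, and that of sterol genes also without vehicle replicate 3 (0.177). That of DNA replication was lost without combination replicate 1 (-0.121) or vehicle replicate 1 (-0.132) or after quantile normalization (-0.122). This call was also lost without the 2 arrays farthest from their groups (-0.132). The miRNA-gene covariate left 5 lists called and ended the calls of DNA replication (-0.049), MYC targets (-0.115), mitotic genes (-0.21) and anti-apoptotic genes (-0.536). Since this covariate overlaps with panobinostat treatment, the source of these losses stays open. Testing without dim genes left 4 and ended those of DNA replication (-0.159), MYC targets (-0.211), anti-apoptotic genes (-0.624), sterol genes (0.192) and p53 targets (0.528).

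**Figure D2:**
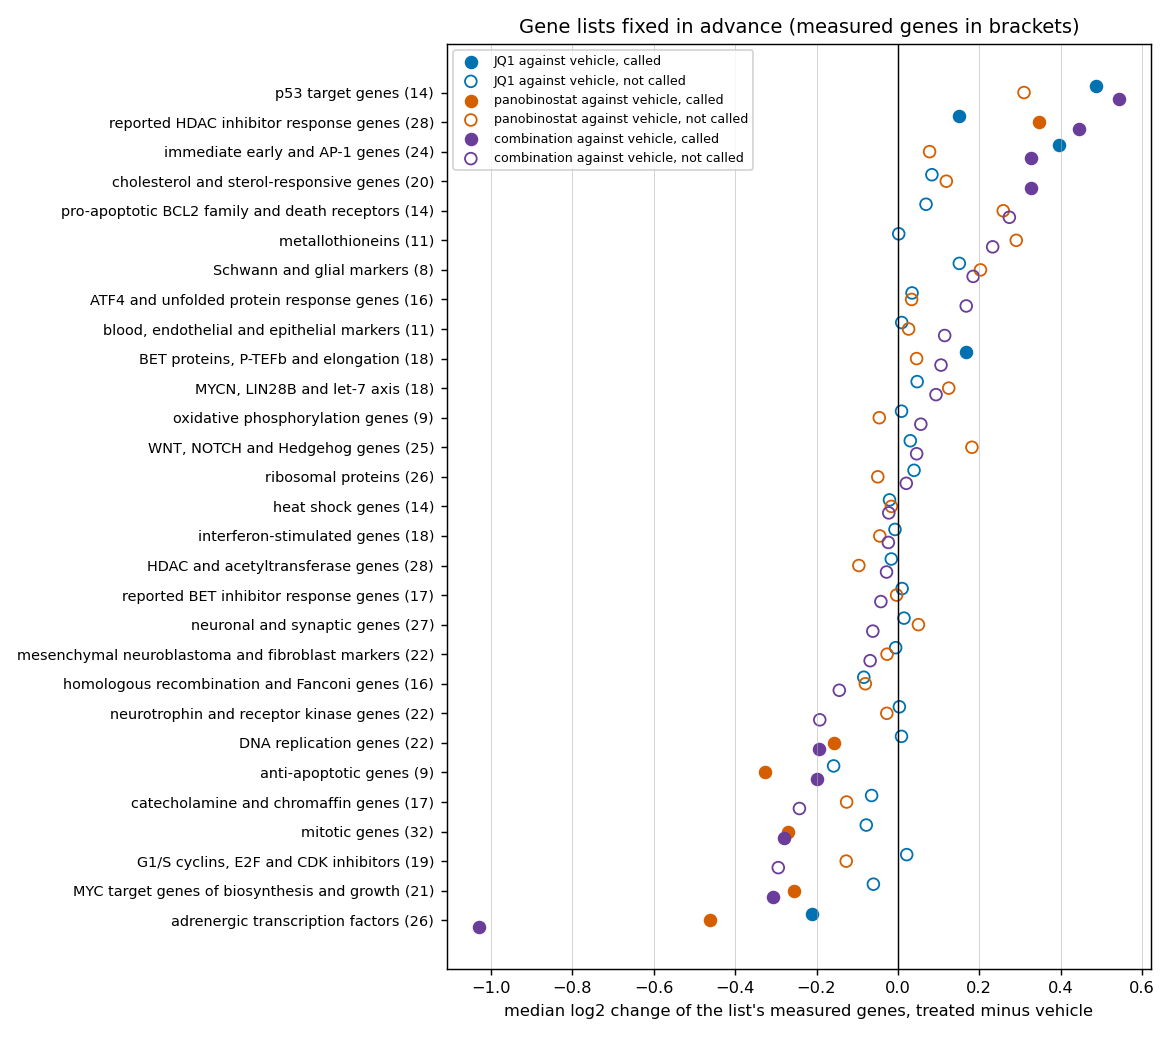
Median log2 change of each gene list's measured members against vehicle for JQ1, panobinostat and the combination, with filled points for lists called by camera at the preset correlation. The adrenergic transcription factors have the lowest median in each comparison, at -0.21, -0.46 and -1.03.

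Genes chosen in advance for their link to the compounds gave mixed changes. BRD2 rose by 0.62 ± 0.10 with the combination and was at 0.04 ± 0.10 with panobinostat (adjusted p = 0.789). BRD3 fell by 0.29 ± 0.06 with panobinostat and was at -0.01 ± 0.06 with the combination (adjusted p = 0.882). The latter value turned positive after quantile normalization (0.032), with the miRNA-gene covariate (0.034) and without vehicle replicate 1 (0.015). HDAC3 rose by 0.58 ± 0.11 with panobinostat and by 0.85 ± 0.11 with the combination, and HDAC1 rose by 0.44 ± 0.07 with the combination. For HDAC1 with panobinostat, the log2 change of 0.26 ± 0.07 (adjusted p = 0.0132) did not pass without panobinostat replicate 3 (0.215) or vehicle replicate 2 (0.227). HDAC2 fell by 0.24 ± 0.07 with the combination (adjusted p = 0.0175), which did not pass without combination replicate 1 (-0.199), combination replicate 2 (-0.236) or vehicle replicate 1 (-0.20), with the miRNA-gene covariate (-0.116) or with the mean of its clusters (-0.313). MYC, a dim transcript here, was at 0.28 ± 0.13 with JQ1 (adjusted p = 0.161), 0.20 ± 0.13 with panobinostat (adjusted p = 0.286) and 0.35 ± 0.13 with the combination (adjusted p = 0.0469). The MYC call for the combination was lost without any 1 of combination replicates 1 (0.356) and 2 (0.267), the JQ1 arrays (0.347 each) and vehicle replicates 1 (0.276) and 3 (0.347). It was also lost with quantile normalization (0.307), a replicate term (0.347) or the covariate (0.205), and MYC passed with panobinostat without its replicate 2 (0.344). The HEXIM1 change with panobinostat (0.44 ± 0.06, adjusted p = 0.000322) was 0.016 and not called when its clusters were averaged.

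**Figure D3:**
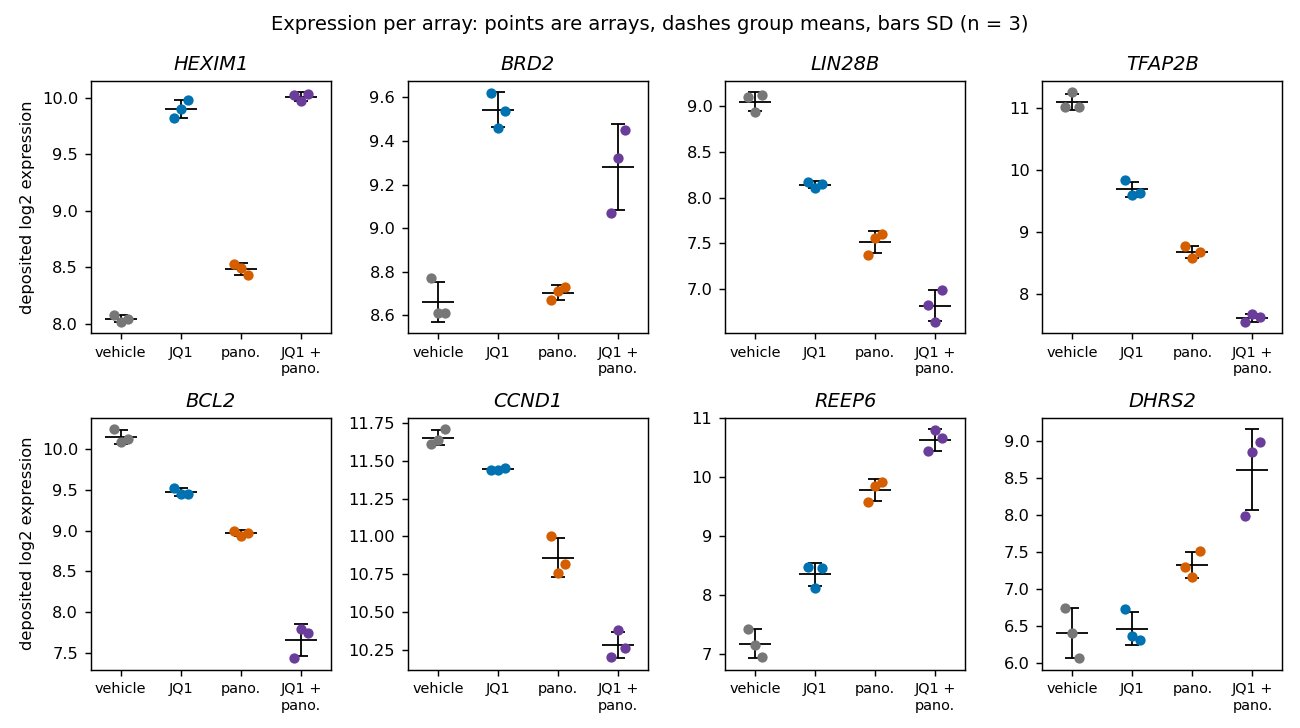
Log2 signal of 8 named genes on each of the 12 arrays, by group, with the group mean and SD. HEXIM1 and BRD2 are higher with JQ1, REEP6 is highest with the combination, and LIN28B, TFAP2B and BCL2 are lowest with the combination.

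The combination was compared with each compound alone to show what the second compound adds. Added to JQ1, panobinostat raised REEP6 (2.27 ± 0.15), DHRS2 (2.15 ± 0.25), CCDC110, a cancer-testis antigen (2.11 ± 0.10), and TEC (2.05 ± 0.22). It lowered TFAP2B (-2.07 ± 0.09), CD200 (-1.95 ± 0.10), BCL2 (-1.82 ± 0.09) and UNC5C, a netrin receptor (-1.78 ± 0.07). Added to panobinostat, JQ1 raised HEXIM1 (1.52 ± 0.06), DHRS2 (1.29 ± 0.25) and SERTAD1, a regulator of CDK4 and E2F activity (1.28 ± 0.15). It lowered FLRT3, an adhesion protein (-1.53 ± 0.14), LRRN3, a neuronal membrane protein (-1.50 ± 0.08), and SYT4, a synaptotagmin (-1.43 ± 0.17). The combination differed from JQ1 in 3816 genes (1744 higher and 2072 lower) and from panobinostat in 2184 (912 higher and 1272 lower). The former split was 2176 higher and 1669 lower with the miRNA-gene covariate and 1684 and 2245 after centring each array on its median. The latter split turned to 1233 higher and 1105 lower with that centring and was 1524 and 1677 with the covariate, and 1325 genes were called when only the arrays of these groups were fitted.

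BCL2, LRRTM1, TFAP2B and LIN28B were among 1042 genes that the combination changed more than either compound did (361 higher and 681 lower). ZNF827, a zinc finger protein, stood at -1.18 ± 0.06 with JQ1, -1.43 ± 0.06 with panobinostat and -2.43 ± 0.06 with both, and HDAC9, a class IIa deacetylase, at -0.54, -0.57 and -1.44, each ± 0.07. Of the 1042 genes, 576 were called in that direction with both single compounds, 185 with neither, and 429 were changed at least 2-fold against vehicle. Fits of only the compared groups gave 672 such genes.

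Panobinostat was compared with JQ1 to separate genes that respond to 1 compound from those that respond to both. MEPCE, which encodes the capping enzyme of 7SK RNA, rose with JQ1 (0.46 ± 0.09) and fell with panobinostat (-1.55 ± 0.09), a difference of -2.01 ± 0.09. SGF29, a subunit of the SAGA acetyltransferase complex, likewise stood at 0.48 ± 0.07 and -1.21 ± 0.07, and SIRT1, a deacetylase, at 0.95 ± 0.07 and -0.29 ± 0.07. PI15, a peptidase inhibitor, showed the reverse (-1.41 ± 0.12 with JQ1 and 0.83 ± 0.12 with panobinostat). EFNA3 was 1.99 ± 0.08 higher with panobinostat than with JQ1, and PATZ1, a zinc finger protein, was at -1.58 ± 0.09. The compounds differed in 3461 genes (1732 higher and 1729 lower with panobinostat), a split that became 1438 higher and 2248 lower after centring each array on its median and 2140 higher and 1479 lower with the miRNA-gene covariate.

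Genes that both compounds changed mostly went the same way. LRRTM1, DKK1, NPY2R, TFAP2B and LIN28B fell and PAG1, AHR, SESN3 and REEP6 rose with each compound. In all, 663 genes were higher with both and 867 lower with both, where independent calls would give 177 and 209. Another 128 genes changed in opposite directions, where 385 would be reached. For each of the 128 the direct difference between the compounds was called too. This follows from opposite calls against the same vehicle arrays in 1 fit and adds no evidence. 1497 of the 1530 genes that both compounds changed the same way changed that way with the combination. The log2 changes of the compounds correlated at r = 0.559 across genes, which are not independent replicates. Both changes share the vehicle arrays, and simulated unchanged groups gave a mean r of 0.499 (0.478 to 0.514 in 100 draws). The covariance was 0.0552 against a simulated mean of 0.00767, and simulated draws gave 0 to 1 genes called the same way with both. Unchanged groups give almost no calls, so the latter number does not show how far shared arrays raise the overlap among changed genes. The share of all genes with the same sign showed no excess, at 66.6% against a simulated mean of 66.6% (65.7% to 67.4%). With the vehicle arrays divided, 1 for one compound and the others for the other, the 6 divisions gave r = 0.337 to 0.456 and 699 to 998 genes called the same way, 4.15 to 5.39 times the number for independent calls. Between 54.3% and 61.5% of all genes then had the same sign.

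The interaction term was tested to find genes whose change with both compounds departed from the sum of the single changes. PAG1 rose with JQ1 and panobinostat but stood at 1.98 ± 0.13 with both, 1.43 below the sum (interaction -1.43, adjusted p = 0.0107). SESN3 (-1.15, adjusted p = 0.00443), AHR (-1.11, adjusted p = 0.00694) and MKNK2 (-0.77, adjusted p = 0.0148) were also below the sum of their rises. Falls were smaller than the sum for NPY2R (0.81, adjusted p = 0.0166), POPDC2 (0.97, adjusted p = 0.00902), and PRDM10, a zinc finger protein (0.98, adjusted p = 0.0107). Departures beyond the sum were rarer: UNC5C had an interaction of -0.82 (adjusted p = 0.00764), MEIS2 of -0.57 (adjusted p = 0.0164), and the BCL2 value of -0.63 did not pass (adjusted p = 0.0545).

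The interaction was called for 113 genes (46 higher and 67 lower), 99 of them opposite in sign to the sum of the single changes and 14 with the same sign. Among genes that both compounds raised, 38 were called and 38 of these were below the sum, and among genes that both lowered, 40 were called and 38 had a smaller fall than the sum. Adrenergic transcription factors were the 1 list called (median -0.31, camera adjusted p = 2.88e-05, and adjusted p = 0.0715 with an estimated correlation). Of its 26 genes 0 were higher and 3 lower (MEIS2, PHOX2A and HAND1), or 3 and 10 adjusted over the list alone. The PHOX2A call (-0.47) was lost in each of the 12 fits that left out an array (-0.511 to -0.428) and that of HAND1 (-0.58) in 10 of them (-0.607 to -0.515), and that of MEIS2 was lost without combination replicate 2 (-0.558), with a replicate block, also one within panobinostat status (-0.571), and with the mean of its clusters (-0.448). The number of genes called was 220 with array weights, 324 with an intensity trend, 282 after quantile normalization, 259 without dim genes, 457 with the miRNA-gene covariate, 48 with a replicate term, 60 with one within panobinostat status and 12 over all clusters. Leaving out vehicle replicates 1, 2 and 3 gave 86, 65 and 60 genes, JQ1 replicates 48, 49 and 62, panobinostat replicates 70, 58 and 56, and combination replicates 71, 28 and 48.

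**Figure D4:**
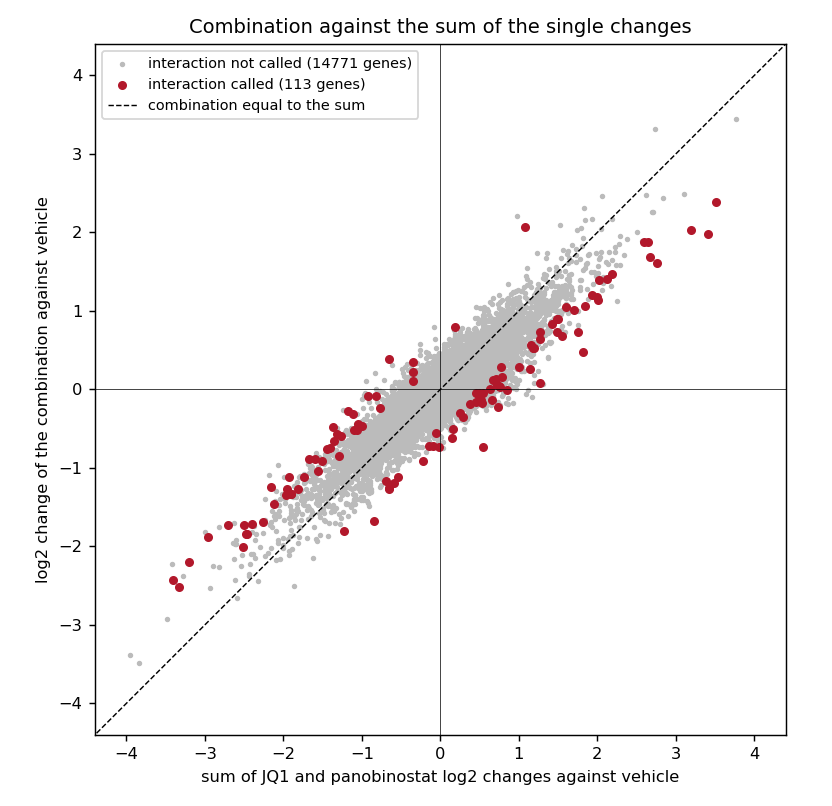
Log2 change with both compounds against the sum of the log2 changes with JQ1 and with panobinostat, 1 point per gene, with the line of equality and the 113 genes with a called interaction in red. Of these 113 genes, 99 lie on the side of the line where the change with both compounds is shifted against the sign of the sum.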

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

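The covariate from the miRNA-gene component, the fits that left out each array for a gene list, the replicate block within panobinostat status, the permutations of residuals, the division of the vehicle arrays and the test of a measurement floor were chosen only after the results were seen. Each gene below is given because its panobinostat effect differed with and without JQ1 (limma interaction), in the unit of log2.

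Among genes that rose with both compounds, the interaction was -1.43 for PAG1 (adjusted p = 0.0107), -1.17 for HSPA2 (adjusted p = 0.0166), -1.15 for SESN3 (adjusted p = 0.00443), -1.11 for AHR (adjusted p = 0.00694), -0.86 for the NOTCH ligand JAG1 (adjusted p = 0.0107) and -0.77 for MKNK2 (adjusted p = 0.0148). It was -0.64 for NPTX2, a neuronal pentraxin (adjusted p = 0.0264) and -0.55 for the growth factor receptor FGFR1 (adjusted p = 0.0239). For the metallothionein MT1B it was -0.63 (adjusted p = 0.048), but its rises with single compounds lost their call after quantile normalization (0.245 with JQ1 and 0.212 with panobinostat) and in 7 and 2 of the 12 fits that left out an array, and that with JQ1 also with a replicate block (0.302). SFRP1, a secreted WNT antagonist, had an interaction of -0.58 (adjusted p = 0.0239). FLRT3 stood at 0.80 with panobinostat alone and -0.73 with both compounds (interaction -1.27, adjusted p = 0.0164). Falls exceeded the sum for UNC5C (-0.82, adjusted p = 0.00764), HAND1 (-0.58, adjusted p = 0.0405), MEIS2 (-0.57, adjusted p = 0.0164) and PHOX2A (-0.47, adjusted p = 0.048).

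Positive values were found for EPC2, a subunit of the NuA4 acetyltransferase complex (0.63, adjusted p = 0.0361), IFIT2, an interferon-induced gene (0.68, adjusted p = 0.0368), NPY2R (0.81, adjusted p = 0.0166), POPDC2 (0.97, adjusted p = 0.00902), PRDM10 (0.98, adjusted p = 0.0107), NHSL2 (1.00, adjusted p = 0.00902) and RD3 (1.08, adjusted p = 0.0164), all of which were lower than vehicle with both compounds. MAP2K6, a kinase that activates p38, was -0.85 with JQ1 and 0.39 with both compounds (1.04, adjusted p = 0.00694). A replicate block ended the calls of FLRT3 (-1.269), MEIS2 (-0.571), FGFR1 (-0.548), SFRP1 (-0.577), HAND1 (-0.577), PHOX2A (-0.468), MT1B (-0.632) and IFIT2 (0.676), and a block within panobinostat status ended all of these except that of IFIT2. Without combination replicate 2 the calls of FLRT3 (-1.24), HSPA2 (-1.17), MEIS2 (-0.558), FGFR1 (-0.558), SFRP1 (-0.565), HAND1 (-0.523), PHOX2A (-0.472), MT1B (-0.629) and IFIT2 (0.666) were lost. Over the 12 fits that left out 1 array, the call was lost in 9 for FGFR1 (-0.558 to -0.513), 8 for SFRP1 (-0.599 to -0.549), 10 for HAND1 (-0.607 to -0.515), 12 for PHOX2A (-0.511 to -0.428), 11 for MT1B (-0.698 to -0.57) and 9 for IFIT2 (0.603 to 0.691). A dimmer RD3 cluster stood at -0.16 with both compounds and was not called. Among the 37519 clusters without a gene name, which no comparison of genes uses, 3849 differed between the combination and vehicle (1963 higher and 1886 lower), against 2300 for panobinostat and 928 for JQ1.

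Of the 100 splits of the 12 arrays into 4 groups of 3, the real one included, 3 gave at least the 113 interaction calls. The highest other split gave 1595, several times the real number, which points to a structure of the samples: it placed the 3 combination arrays as vehicle and the 3 JQ1 arrays as the combination, and mixed vehicle with panobinostat arrays in the other groups. For the genes changed more by the combination than by either compound (1042) and those changed the same way by both (1530), 1 of 100 splits, the real one, was as large, and the highest others gave 27 and 726. At least 1 list was called for the interaction in 79 splits, with up to 11 beside the real 1. Such splits mix treatments within groups, which raised the median residual SD above the real one in 99 of 99 and turns treatment effects into noise or interactions, so they do not decide whether chance gives any of these 4 numbers.

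Permuting residuals leaves the modelled effects in place. Around additive effects, 3 of 100 permutations, the real order included, gave at least 113 interaction calls, which argues against noise around additive effects as the whole source of the number. The highest other permutation gave 479 calls, so the arrays' noise can also yield more than the real number. With the combination set to the larger single effect of each gene, 1 of 100 permutations, the real order, reached 1042 genes and the highest other gave 633. This argues against noise on top of the larger single effect as the whole source of that number. These permutations treat the arrays as exchangeable, and a block within panobinostat status gave 60 interaction calls. For the genes changed the same way by both compounds, the vehicle arrays were divided between the comparisons. This left a correlation of at least 0.337 and at least 4.15 times the number for independent calls. These values argue against error of single shared vehicle arrays as the whole cause. A deviation common to all vehicle arrays would stay in every division, so that source remains open.

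Adrenergic transcription factors were lower with both compounds than the sum of the single changes, with a median interaction of -0.31 over 26 genes, and 0 of 10000 random lists matched on mean signal had a median as low, which argues against the brightness of the genes as the cause. The mean of -0.22 stayed at -0.201 or below whichever array was left out (weakest without JQ1 replicate 1), which argues against a single deviating array. With the miRNA-gene component as covariate it was -0.222, but that covariate moved the interaction of the median gene by only 0.0130 against a median size of 0.137, so this value decides nothing. The list stayed the 1 list called after quantile normalization and after centring each array on its median. This argues against differences in the arrays' distribution of values as the whole source of the call. Any other array-wide measurement difference stays open. Chance cannot be excluded for the call of a list as such, since 51 of 100 permutations around additive effects, the real order included, called at least 1 list and up to 6, and the call was lost with an estimated correlation (adjusted p = 0.0715). A combined effect of the compounds on this network may lie behind the pattern, but with these points open it remains a hypothesis, and additivity on the log scale is itself a choice.

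Most interaction calls ran against the sum of the single changes (99 of 113), which could arise from error shared between the terms. Genes were selected by single changes from 1 array per group, in the same direction and at least 0.5 in size (760 to 797 genes). They were taken whether or not their interaction was called. With the interaction from the other arrays, at least 71.9% of them ran against the sum in each of 3 partitions. This argues against error of single arrays as the whole cause for the selected genes, but the 113 called genes were not tested apart. A deviation common to all vehicle arrays would enter every partition alike, so the partitions do not decide on it. Some of the selected genes fell but had a level, predicted by the sum from the arrays outside the interaction, above the median signal. Among these the share against the sum was at least 77.5% in each partition. This argues against a measurement floor for those genes and leaves it open for dimmer ones. With the miRNA-gene covariate 87.5% of the interaction calls ran against the sum. This value decides nothing, because the covariate hardly moved the interaction. After quantile normalization, which gives all arrays the same distribution of values, 250 of 282 calls did so (88.7%), and after median centring 87.6%. This argues against differences in the arrays' distribution of values as the whole cause. Any other array-wide measurement difference cannot be told apart from an effect of the compounds here. Compression of bright rising signals was not tested, and a saturating response to overlapping effects of the compounds stays among the open explanations, untested.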

How the results depend on the processing

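The miRNA-gene covariate, the fits without vehicle replicate 1 and panobinostat replicate 1, the list tests that left out an array, the replicate block within panobinostat status and, for the overlap, the 2-fold minimum, all clusters, array weights, the trend, fits of the compared arrays and quantile normalization were chosen only after the results were seen. Total counts that are not given here stayed within 1.5 times their value under every setting run for them, but by direction the covariate gave 1882 genes higher with JQ1 than with vehicle instead of 1218, and 1524 higher with the combination than with panobinostat instead of 912. A minimum change of 2-fold, which leaves fewer genes by construction, gave 129 genes for JQ1, 297 for panobinostat and 761 for the combination against vehicle, 196 for the combination against JQ1, 46 against panobinostat, 144 for panobinostat against JQ1, 13 changed more than by either compound, 55 changed the same way by both and 10 for the interaction. Testing all named and unnamed clusters, a wider set, gave 6707 for panobinostat, 9587 for the combination and 12 for the interaction. With only the compared arrays in the fit, and so fewer degrees of freedom, 1325 genes differed between the combination and panobinostat and 672 were changed more than by either compound. Interaction calls numbered 220 with array weights, 457 with the covariate, 259 without genes below the 40th percentile of signal, 324 with an intensity trend and robust prior, 282 after quantile normalization and 48 with a replicate term, and 28 to 86 when 1 array was left out. Of the 113 genes, 113, 99, 109, 107 and 43 were among those called with the covariate, without dim genes, with the trend, after quantile normalization and with the replicate term. List calls fell from 5 to 0 for JQ1, from 6 to 1 for panobinostat, from 9 to 1 for the combination and from 1 to 0 for the interaction with an estimated correlation, and fry, which asks another question, called 11, 19, 21 and 3. For the combination the covariate left 5 list calls and the filter on dim genes 4, and that filter gave 3 for the interaction. The BRD3 value with the combination, which was not called, changed sign with the covariate (0.034), after quantile normalization (0.032) and without the 2 arrays (0.015), and ranged from -0.051 to 0.015 when 1 array was left out, and that of HDAC2 with panobinostat, also not called, changed sign with the covariate (0.024). The component differed by -0.480 between the groups with and without panobinostat and separated their arrays completely. Arrays without panobinostat lay at 0.107 to 0.588 and those with it at -0.451 to -0.015. The covariate may therefore also take up treatment signal, which was not tested, and calls lost with it do not tell a measurement difference from treatment. Apart from the 2-fold minimum, the cause of the changes in this paragraph was not tested. Of the 397 values of named genes, 391 kept direction and call with median centring, 390 with quantile normalization, 372 with the replicate term, 391 with the mean of a gene's clusters, 369 with the covariate and 366 without the 2 arrays. Of 18 pairs of arrays with the same number, 4 had a residual correlation over 0.1 (-0.693 to 0.236) and 0 of 12 arrays correlated best with their own number, so the numbers do not pair the samples across the 4 groups, but the 6 pairs with the same panobinostat status were all above 0 (0.083 to 0.236). A replicate block within that status called 2802 genes for JQ1 against vehicle, 2314 for the combination against panobinostat and 60 for the interaction, 48 of them among the 113. It kept the call and direction of 129 of 140 values of named genes and ended 11 calls. A larger pseudocount was not run, since the table is on a log scale. The values carry no background estimate, so how far dim genes such as MYC lie above background is unknown.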

Other observations

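The tests of the shared component of the arrays were chosen only after it was seen.

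With the combination, camera did not set the lists of receptors, developmental signals and cell identity apart from other genes, and limma called 37.72% of all genes. Of 22 neurotrophin and receptor kinase genes 9 fell and 4 rose (camera adjusted p = 0.109), with GFRA2, a co-receptor of neurturin, at -1.89 ± 0.09, EGFR at -1.11 ± 0.09 and the VEGF receptor KDR at 0.97 ± 0.11. Of 25 WNT, NOTCH and Hedgehog genes 8 rose and 4 fell (adjusted p = 0.477), with the NOTCH target HEY2 at 1.47 ± 0.24, JAG1 at 1.14 ± 0.08 and HEY1 at -1.03 ± 0.10. Of 17 catecholamine and chromaffin genes 9 fell and 2 rose (adjusted p = 0.0628), with the secretogranin SCG2 at -1.41 ± 0.08 and GCH1, which makes the cofactor of tyrosine hydroxylase, at 1.03 ± 0.09. Among 27 neuronal and synaptic genes 8 rose and 6 fell (adjusted p = 0.841), with SYN1 at 1.41 ± 0.13, VGF at 1.34 ± 0.11 and SYT4 at -2.36 ± 0.17. Of 22 mesenchymal and fibroblast markers 4 rose and 6 fell (adjusted p = 0.456), of 8 Schwann and glial markers 2 rose and 0 fell (adjusted p = 0.111), and of 11 blood, endothelial and epithelial markers 1 rose and 0 fell (adjusted p = 0.548). The transcription factor SNAI2, of the mesenchymal list, fell by 0.97 ± 0.07. Fry, which asks for movement on balance without comparing with other genes, called the receptor kinase list lower (adjusted p = 4.46e-06), catecholamine genes lower (1.7e-06), mesenchymal markers lower (0.0148) and Schwann and glial markers higher (7.03e-05).

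Lists of chromatin, growth control, repair and cell death held genes of both directions with the combination. Of 28 HDAC and acetyltransferase genes 11 rose and 12 fell (adjusted p = 0.868), with HDAC9 at -1.44 ± 0.07, CREBBP, an acetyltransferase, at -1.07 ± 0.07, SIRT7 at 1.15 ± 0.08 and the corepressor SIN3A at 1.09 ± 0.08. Genes reported to respond to BET inhibitors rose in 4 of 17 cases and fell in 6 (adjusted p = 0.717), and in the list of BET proteins, P-TEFb and elongation 7 of 18 rose and 4 fell (adjusted p = 0.384). G1/S genes fell in 10 of 19 cases and rose in 6 (adjusted p = 0.111), with E2F2 at -1.15 ± 0.10 and the cyclin gene CCNE1 at 1.10 ± 0.10. Homologous recombination and Fanconi genes fell in 7 of 16 cases and rose in 1 (adjusted p = 0.062), with NBN at -1.35 ± 0.10 and RAD51AP1 at -1.01 ± 0.12. Pro-apoptotic genes rose in 8 of 14 cases and fell in 1 (adjusted p = 0.0528), with BNIP3L at 0.88 ± 0.06 and APAF1 at 0.81 ± 0.11. In the list of MYCN, LIN28B and let-7 genes 6 of 18 rose and 3 fell (adjusted p = 0.705), with MXD1, a MAX partner that opposes MYC, at 1.85 ± 0.11 and the RNA-binding protein gene IGF2BP3 at -1.72 ± 0.10. Fry called the lists of BET inhibitor response (adjusted p = 0.00975), G1/S (0.000317) and recombination genes (0.0069) lower, and those of BET proteins and P-TEFb (0.000143) and pro-apoptotic genes (0.000102) higher. For the BET inhibitor response list the direction by fry depended on the compound. It was higher with JQ1 alone (fry adjusted p = 0.000879) and lower with panobinostat alone (fry adjusted p = 0.000659).

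ATF4 and unfolded protein response genes rose in 6 of 16 cases and fell in 4 with the combination (adjusted p = 0.377), with the stress sensor ERN1 at 1.45 ± 0.11. Heat shock genes rose in 5 of 14 cases and fell in 1 (adjusted p = 0.264), with HSPA1A at 0.84 ± 0.07. Metallothioneins rose in 4 of 11 cases and fell in 0 (adjusted p = 0.109), with MT2A at 0.89 ± 0.09. Interferon-stimulated genes rose in 2 of 18 cases and fell in 3 (adjusted p = 0.933), with IRF7 at 1.06 ± 0.09. Fry called the ATF4 (adjusted p = 0.00559), heat shock (0.000317) and metallothionein (0.00559) lists higher. Ribosomal protein genes rose in 2 of 26 cases and fell in 1 (adjusted p = 0.733), and of 9 oxidative phosphorylation genes 0 rose and 0 fell (adjusted p = 0.841 by camera). None of the lists in these paragraphs except that of BET proteins and P-TEFb was called by camera with a single compound, where the lowest adjusted p was 0.17 for JQ1 (catecholamine genes) and 0.106 for panobinostat (pro-apoptotic genes), and in the interaction the lowest was 0.136 (neurotrophin and receptor kinase genes). Median, mean and test differed in sign for some of them, as in the MYCN, LIN28B and let-7 list, with a median of 0.09, a mean of -0.004 and an upward test direction for the combination, and for heat shock genes, with a median of -0.02, a mean of 0.24 and an upward direction.

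For the comparisons of 3 with 3 arrays the 10 possible splits are too few for a share under 0.05, and in each 1 split, the real one, gave the largest number. Each other split mixes arrays of both groups, which shrinks their difference and adds it to the residual spread. Low numbers in those splits therefore do not decide whether chance gives the real ones. The highest other split called 0 genes against 2627 for JQ1, 5 against 4363 for panobinostat and 0 against 5614 for the combination. It called 0 against 3816 for the combination and JQ1, 0 against 2184 for the combination and panobinostat, and 1 against 3461 for panobinostat and JQ1. For the list tests the highest other split called 3 lists against 5 for JQ1, 5 against 6 for panobinostat and 7 against 9 for the combination.

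After the group means were removed, 1 component held 36.5% of the remaining variance. Along it vehicle replicate 1 (0.526) lay farthest from panobinostat replicate 1 (-0.455). Replicate 1 of JQ1 (0.206) and of the combination (-0.348) had the sign of the group with the same panobinostat status. Replicates 2 and 3 had the opposite sign in each group. They were at -0.316 and -0.209 for vehicle and -0.145 and -0.06 for JQ1. For panobinostat they were at 0.149 and 0.306, and for the combination at 0.113 and 0.235. Along this component the arrays with and without panobinostat thus differed the other way in replicate 1. The genes' loading on it correlated with their mean signal (Spearman 0.475 across genes, which are not independent replicates), with medians of -0.199 in the dimmest of 5 equal groups of genes and 0.0984 in the brightest. A signal-dependent measurement difference between arrays is therefore a candidate explanation. Same-numbered arrays deviated alike within the groups without and within those with panobinostat (mean residual correlation 0.164 over 6 pairs, 1 of 36 orders of the numbers as large, the real one), so a day or batch shared by a number there may lie behind the component too. Across panobinostat status 11 of 12 same-numbered pairs correlated negatively, down to -0.693, which argues only against a day or batch that shifted the 4 groups alike. No biological explanation was tested, since the labels give nothing but the replicate number that sets arrays of a group apart. Whether the effect of panobinostat differed between replicate numbers was not tested either.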
